A study of Mus musculus with 5 samples.

How the data were processed

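Total RNA sequencing was carried out on whole hearts of mouse embryos at embryonic day 17 on the C57BL/6 background. The 5 libraries comprised 3 wild-type (WT) hearts and 2 hearts with a cardiomyocyte-specific deletion of Prdm16 (cPrdm16 KO), grouped by the sample titles. Library numbers in the titles run from 1 to 4 and then 6; no library numbered 5 was analysed here, and whether one was made is not given in the sources used here. The genotype tag of the second cPrdm16 KO sample reads KO1 where its title reads KO2; the title was used, and the 2 samples have count columns of their own that differ by more than counting noise. Nothing in the labels says whether the hearts came from separate litters, and no sex, batch or dissection note is given, so p-values measure the spread between these samples.

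The deposited values are raw counts per Ensembl gene, made by the authors from TruSeq Stranded libraries depleted with Ribo-Zero Gold, per the labels' protocols. Per the submitters' processing notes, the build was GRCm38 and the tools were cutadapt 1.16, STAR 2.6.1b, featureCounts 1.6.3 and DESeq2 1.20.0. The annotation release, the strand setting and the treatment of multi-mapping reads are not given in the sources used here. Genes that share exons with an antisense or overlapping gene, or that have a near-identical paralog, can therefore exchange reads and are named as uncertain. The table held 54532 genes, of which 54409 were paired with a symbol through the GENCODE annotation of the same build. No entry lay outside a gene, and 1 symbol of the fixed gene lists, Ahsp, was not matched.

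Library totals ranged from 12869633 to 17131519 counts. Genes were kept with filterByExpr, which left 16183 genes, and library sizes were scaled with TMM factors. The 2 groups were compared with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood functions glmQLFit and glmQLFTest with default settings and no covariate. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 are said to have risen, fallen or changed. The common biological coefficient of variation was 0.190 and the prior degrees of freedom were 5.51. Levels are TMM-normalised CPM (counts scaled to a common library size) with their SD, and fold changes are log2 values of cPrdm16 KO against WT with a standard error (SE) equal to the fold change divided by the square root of its F statistic. Prdm16 was also tested by an exact 2-sided permutation over the 10 assignments of the 5 libraries, which cannot give a p under 0.1.

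Before the data were examined, lists of genes were written from textbook knowledge. They covered the myocardium (compact, trabecular and conduction, fetal and stress genes, adult sarcomere, calcium handling, ion channels, cardiac transcription factors). They covered metabolism (fatty acid oxidation, oxidative phosphorylation, mitochondrially encoded genes, tricarboxylic acid cycle, glycolysis, mitochondrial regulators and the brown fat program) and the PRDM family. Signaling and structural lists covered TGF-beta, BMP, Notch, Neuregulin and FGF, collagens and extracellular matrix, and cell junctions. Further lists covered the cell cycle (S, and G2 and M), p53 targets, the integrated stress response, hypoxia, interferon, immediate early genes and ribosomal proteins. Cell type lists covered atrial and ventricular cardiomyocytes, fibroblasts, epicardium, endothelium, endocardium, lymphatic endothelium, smooth muscle and pericytes, neural crest and Schwann cells, macrophages, neutrophils and lymphocytes, erythroid cells, platelets, skeletal muscle, lung epithelium, thymus and liver, and adipocytes. The 43 lists with at least 3 tested members were tested with camera from limma 3.58.1, 2-sided, with its preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. A list of sex-linked genes served as a check without a set test. The lung epithelium list had 0 tested members and the adipocyte list had 1, so neither was tested as a set.

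The genes named were chosen by a rule fixed with the lists. It took Prdm16, then the 8 largest rises and the 8 largest falls among changed genes with a mean of at least 1 CPM and both cPrdm16 KO libraries on one side of all WT libraries. Provisional symbols, pseudogenes and sex-linked genes were left out of that ranking. It also took up to 4 changed members of each list by smallest p, or the member with the smallest p where none changed, and Nppa, Nppb, Myh6, Myh7, Tgfb2 and Ppargc1a.

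The procedure was tested on simulated counts for the 16183 genes, with 200 changed genes in each of 5 runs. It recovered 49.3% of genes changed by 2-fold and 89.4% of genes changed by 4-fold, against 6.57% of genes changed by 1.5-fold, and it called 0.106% of unchanged genes. A list shifted by -0.5 was called in 5 of 5 runs, and 4 of 205 tests of other lists passed. The simulated genes varied independently of each other, so these list rates do not cover lists whose genes move together. Changes under 2-fold were thus often below what 5 libraries can detect.

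The alternatives were DESeq2 1.42.0, limma-voom, median-ratio factors, library sizes without mitochondrially encoded genes, no filter, a filter of 1 CPM in 3 libraries, robust empirical Bayes, and each library left out in turn. A block on the replicate number, a test against a fold of 1.2, an adjusted p under 0.01, camera with an estimated correlation and fry completed the planned set. Alternatives chosen after the data were seen left out the X and Y genes, left out WT2 and WT3, or added the level of hepatocyte or of atrial transcripts as a covariate.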

Results

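Gene expression was measured by total RNA sequencing in whole hearts of mouse embryos at embryonic day 17. Hearts of 3 WT embryos (WT1, WT2 and WT3) were compared with hearts of 2 embryos in which Prdm16, a zinc finger transcription factor with a PR domain, had been deleted in cardiomyocytes (KO1 and KO2). The study asks how the loss of Prdm16 in these cells changes the transcripts of the developing heart. Total counts were 16674834, 13164438 and 17131519 in WT1, WT2 and WT3, and 12869633 and 13388769 in KO1 and KO2. Between 23451 and 24524 genes had at least 1 count in a library. Ttn, which encodes the giant sarcomere protein titin, took 6.61% to 7.99% of the counts, and the mitochondrial ribosomal RNA mt-Rnr2 took 0.191% to 2.39%. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 28.2 for WT2 against WT3 and 30.8 for KO1 against KO2, so each library was counted as its own sample. By Pearson correlation of log CPM, WT1 was closer to KO1 (0.974) than to WT2 (0.968) or WT3 (0.962). The other libraries correlated best with a library of their own group.

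Prdm16 itself (ENSMUSG00000039410; GRCm38 chromosome 4, 154316125 to 154636873, minus strand) was not called lower. Its level was 18.9 ± 4.13 CPM in WT (SD, n = 3) and 14.1 ± 3.32 CPM in cPrdm16 KO (SD, n = 2), which is 74.5% of the WT level. The log2 change was -0.43 (SE 0.24, adjusted p = 0.496), and an exact permutation test gave p = 0.3, where 0.1 is the smallest value possible. The groups overlapped, since KO2 had 16.4 CPM and WT2 had 14.1 CPM. Counts over the whole gene do not show which exons were deleted, and cells other than cardiomyocytes keep the gene in whole hearts, so these counts do not check the genotype labels. Prdm16 shares exon sequence with B230104I21Rik.

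The sex-linked transcripts separated the groups completely. Xist, the noncoding RNA of the inactive X chromosome, lay between 1242 and 1638 CPM in the 3 WT libraries and between 0.296 and 0.510 CPM in the 2 cPrdm16 KO libraries. The Y-linked Ddx3y had 5122 counts in cPrdm16 KO and 3 in WT, a depth-adjusted ratio of 2860 with a 95% counting interval of 978 to 13873, and such intervals cover counting error only. Eif2s3y had 3403 counts against 2 and Uty had 3749 against 2. The sex of the embryos is not in the labels, and by these transcripts sex and genotype coincide in all 5 libraries, so the comparison of genotypes is at the same time one of sexes.

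In cPrdm16 KO hearts, transcripts typical of atrial myocardium were higher, and those of ventricular myocardium and of mitochondrial energy metabolism were lower. The list tests behind this passed with a preset correlation between genes and were lost with an estimated one, with adjusted p = 0.624 with an estimated correlation for atrial genes and adjusted p = 0.399 for ventricular and oxidative phosphorylation genes. Nppa, which encodes atrial natriuretic peptide, rose from 909 ± 570 CPM in WT (SD, n = 3) to 5822 ± 676 CPM in cPrdm16 KO (SD, n = 2), a 6.40-fold increase. Hey2, a transcriptional repressor of ventricular myocardium, fell from 104 ± 3.24 to 55.6 ± 6.01 CPM. Acadm, the medium-chain acyl-CoA dehydrogenase of fatty acid oxidation, fell from 436 ± 37.0 to 208 ± 21.5 CPM. Rag1, a subunit of the recombinase that assembles the antigen receptors of developing lymphocytes, rose, and so did 3 of the 33 matrix genes listed. The call of Nppa was lost without KO1 (adjusted p = 0.192) or KO2 (0.129) and with robust empirical Bayes (0.175). The calls of Hey2 and Acadm were lost without WT3 (0.0704 and 0.0599), KO1 (0.179 and 0.158) or KO2 (0.107 for both).

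Of the 16183 genes tested, 181 changed (adjusted p under 0.05), 134 upward and 47 downward, and 2264 had an unadjusted p under 0.05. Autosomal genes made up 168 of them, with 126 higher and 42 lower in cPrdm16 KO. The changes were often large, with 113 of the higher genes and 27 of the lower genes at 2-fold or more. In all 181 genes both cPrdm16 KO libraries lay on one side of all 3 WT libraries, a separation that the test itself favours. It held for 31.0% of the tested genes and is reached by 20% by chance, a share that varies more where genes move together. The count fell to 28 without KO1, to 14 without KO2 and to 74 without WT3, while DESeq2 called 657 genes, robust empirical Bayes 319 and 383 were called without a filter. Of the 46 changed genes named, 39 lost their call in at least 1 of the 5 fits that left out a library. With the level of atrial transcripts as a covariate, which was added after the data were seen, 1 gene remained, Xist, while the median size of the 181 log2 changes went from 1.504 (median SE 0.23) to 1.27 (median SE 0.35). The atrial level itself differed between the groups, above WT1, WT2 and WT3 in both KO1 and KO2, so this covariate overlaps with the genotype.

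**Figure D1:**
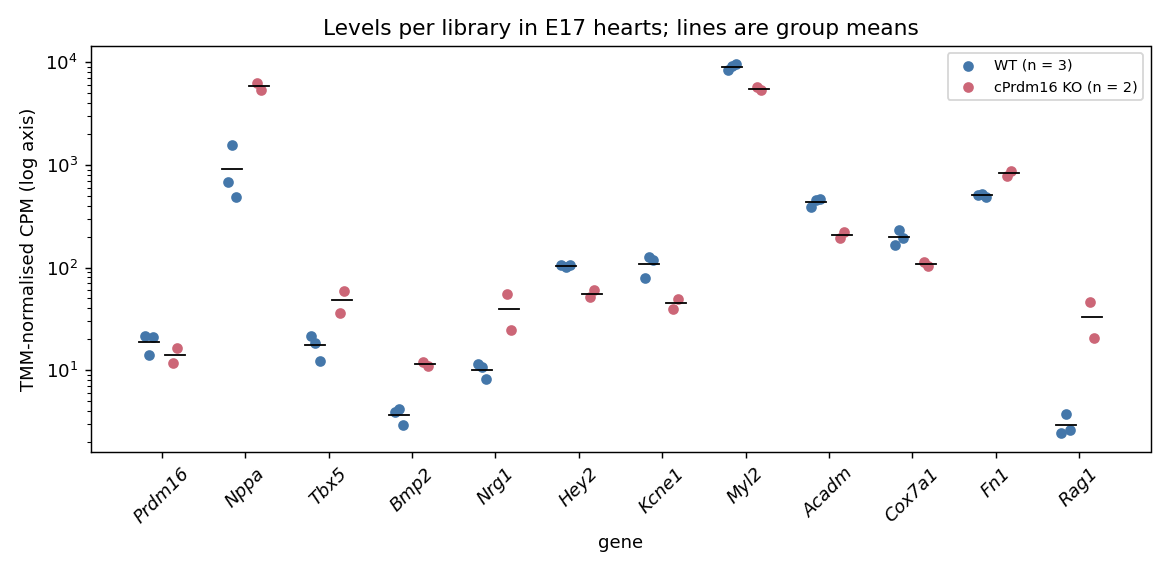
TMM-normalised CPM on a log axis for 12 genes, each point a library (3 WT, blue; 2 cPrdm16 KO, red) and each line a group mean. Nppa averaged 909 CPM in WT and 5822 CPM in cPrdm16 KO with no overlap of the groups, whereas the groups overlapped for Prdm16.

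Among the ranked genes with more than 3 WT counts, the largest rise was that of Alox8 (ENSMUSG00000020891; chromosome 11, 69183932 to 69197843), which encodes a lipoxygenase, from 0.783 ± 0.532 to 37.1 ± 10.2 CPM (log2 change 5.60, SE 0.42, adjusted p = 0.00124). Atp1b4, on the X chromosome, rose by 5.44 (SE 0.48), Ppp1r17 by 4.61 (SE 0.35), the receptor tyrosine kinase gene Alk by 4.46 (SE 0.43) and Luzp2 by 3.95 (SE 0.48). The neighbouring olfactory receptor genes Olfr313 and Olfr312 also rose. Olfr313 had 72 counts in cPrdm16 KO and 2 in WT, a ratio of 60.3 with a 95% counting interval of 16.1 to 507. Olfr312 rose by 4.98 (SE 0.67), and both are uncertain because close paralogs can share reads. The same holds for the lysozyme gene Lyz1, which rose by 3.76 (SE 0.40) next to its paralog Lyz2. Without 1 library, Atp1b4 (without WT2, 6.33), Luzp2 (without WT2, 4.58), Olfr312 (without WT3, 4.37, or KO1, 4.34) and the fitted change of Olfr313 (without WT1, 8.22 against 5.67) moved by more than 1.5-fold. The calls of Luzp2, Olfr312, Olfr313 and Lyz1 were lost without KO1 or KO2 (adjusted p from 0.0761 to 0.184), and those of Alk (0.0693) and Atp1b4 (0.0521) without KO2. Alox8, Ppp1r17 and Rag1 were the autosomal genes among the 46 changed named genes that stayed past the threshold whichever library was left out.

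Among the ranked falls, which leave out sex-linked genes such as Xist, the antisense transcript Banf2os had the largest log2 change, -2.46 (SE 0.44), from 1.85 to 0.331 CPM. Cacng6, a gamma subunit gene of voltage-gated calcium channels, fell from 9.15 ± 1.25 to 1.95 ± 0.904 CPM. Aqp7, a channel for water and glycerol, fell from 2.70 to 0.624 CPM. Ckmt2, the sarcomeric mitochondrial creatine kinase, fell from 231 ± 57.6 to 71.9 ± 12.8 CPM (log2 change -1.69, SE 0.23, adjusted p = 0.0193). Wdr72 changed by -1.57 (SE 0.24), the noncoding Eprn by -1.54 (SE 0.25), Epn3 by -1.48 (SE 0.22) and the growth factor gene Fgf16, which lies on the X chromosome, by -1.47 (SE 0.27). Exons of Ckmt2, Casq1, Xirp2, Nrg1, Acadvl, Lck, Myl2, Myh6, Myh7, Tgfb2, Tgfb3, Ckm, mt-Co1, Cdc20, Higd1a and Xist overlap those of another annotated gene, and Banf2os is annotated antisense, with the strand setting of the counts not given, so their values are uncertain to that extent. The calls of Banf2os, Aqp7 and Fgf16 were lost in each of the 5 fits that left out 1 library, with adjusted p between 0.0543 and 0.306. Those of Ckmt2, Cacng6 and Epn3 were lost without KO1 or KO2 (0.0670 to 0.184), and those of Wdr72 and Eprn without WT2, WT3, KO1 or KO2 (0.0512 to 0.201).

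The atrial cardiomyocyte list lay higher in cPrdm16 KO, with a median log2 change of 1.26 and 13 of 13 members higher. Nppa (ENSMUSG00000041616; chromosome 4, 148000722 to 148002079; log2 change 2.68, SE 0.42, adjusted p = 0.0294) and Tbx5, a T-box transcription factor of the atria and left ventricle (1.46, SE 0.27, adjusted p = 0.0463), rose. The call of Tbx5 was lost without WT2 (adjusted p = 0.0984), WT3 (0.0920), KO1 (0.109) or KO2 (0.255), and that of Nppa without KO1 (0.192) or KO2 (0.129), while without WT2 the log2 change of Nppa was 3.32. The other 11 members did not pass, and 6 rose when p was adjusted over the list alone. Camera gave an adjusted p of 3.5e-06 for the list, which became adjusted p = 0.624 with an estimated correlation. WT libraries also differed in this list, with a median log2 level relative to the WT mean of 0.87 in WT2 and -0.82 in WT3, against 1.37 in KO1 and 1.74 in KO2. Nppa overlaps Gm13054.

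The ventricular cardiomyocyte list lay lower, with a median of -0.70 and 10 of 11 members lower. Hey2 (log2 change -0.91, SE 0.13, adjusted p = 0.0210) and Kcne1, a subunit of a delayed rectifier potassium channel (-1.27, SE 0.22, adjusted p = 0.0389), fell, 9 members did not pass, and 9 fell when adjusted over the list alone. The call of Kcne1 was lost without WT2 (adjusted p = 0.0747), WT3 (0.0920), KO1 (0.279) or KO2 (0.169), and that of Hey2 without WT3 (0.0704), KO1 (0.179) or KO2 (0.107). Camera gave 5.1e-07, and adjusted p = 0.399 with an estimated correlation. Myl2, the ventricular regulatory myosin light chain, had 9066 ± 547 CPM in WT and 5531 ± 220 CPM in cPrdm16 KO without passing the test (adjusted p = 0.0632). The adult sarcomere list had a median of -0.35 with 25 of 26 members lower, 0 changed, and 4 fell when adjusted over the list alone (camera adjusted p = 4.5e-06, and adjusted p = 0.443 with an estimated correlation). Trabecular myocardium and conduction genes had a median of 0.30 with 15 of 17 members higher, of which Nppa rose, and 5 rose when adjusted over the list alone (camera adjusted p = 0.000426, and adjusted p = 0.399 with an estimated correlation).

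**Figure D2:**
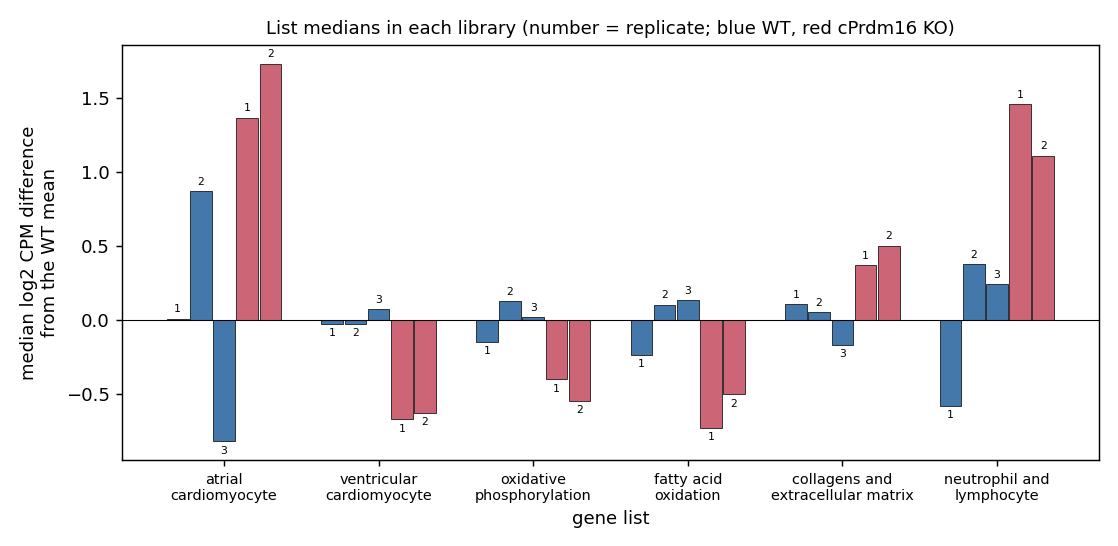
Median log2 CPM of 6 fixed gene lists in each library relative to the mean of the 3 WT libraries, with WT in blue and cPrdm16 KO in red. The atrial list reached 1.37 and 1.74 in KO1 and KO2 and 0.87 in WT2, and the oxidative phosphorylation list lay at -0.40 and -0.55 in KO1 and KO2.

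Genes of mitochondrial energy metabolism were lower in cPrdm16 KO. In the oxidative phosphorylation list, 78 of 79 members were lower with a median log2 change of -0.48. Ndufa5 of complex I (-0.70, SE 0.13) fell, as did Cox7a1 (-0.87, SE 0.16) and Cox8b (-0.72, SE 0.13), the muscle isoforms of cytochrome c oxidase subunits. The call of Ndufa5 was lost whichever library was left out, with adjusted p between 0.0644 and 0.282. The calls of Cox7a1, Cox8b, Acadvl, Eci1 and Suclg2 were lost without WT2, WT3, KO1 or KO2 (0.0806 to 0.299), and that of Acadm without WT3, KO1 or KO2 (0.0599 to 0.158). With the level of hepatocyte transcripts as a covariate, added after the data were seen, Ndufa5, Cox7a1, Cox8b, Eci1 and Suclg2 also lost their calls (adjusted p from 0.0523 to 0.0822). Their log2 changes were -0.68, -0.82, -0.67, -0.84 and -0.69 with the covariate and -0.70, -0.87, -0.72, -0.92 and -0.74 without it. The oxidative phosphorylation, fatty acid oxidation and tricarboxylic acid cycle lists still passed with it, at medians of -0.46, -0.49 and -0.45. The remaining 76 members of the oxidative phosphorylation list did not pass, and 59 fell when adjusted over the list alone. In the fatty acid oxidation list all 30 members were lower with a median of -0.58. Acadm (-1.07, SE 0.14), the very long-chain dehydrogenase Acadvl (-0.88, SE 0.16) and the isomerase Eci1 (-0.92, SE 0.16) fell, 27 did not pass, and 19 fell when adjusted over the list alone. The tricarboxylic acid cycle list had a median of -0.45 with 18 of 18 members lower. Suclg2, a subunit of succinyl-CoA ligase, fell from 82.1 ± 8.42 to 49.2 ± 0.332 CPM, 17 did not pass, and 10 fell when adjusted over the list alone. Camera gave adjusted p values of 9.7e-25, 2.93e-13 and 1.54e-07 for these 3 lists. These became adjusted p = 0.399 with an estimated correlation for oxidative phosphorylation and the tricarboxylic acid cycle, and adjusted p = 0.443 for fatty acid oxidation.

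Glycolysis genes had a median of -0.29 with 19 of 25 members lower. Slc16a1, a monocarboxylate transporter, fell from 404 ± 19.1 to 239 ± 0.236 CPM, 24 members did not pass, and 3 fell when adjusted over the list alone (camera adjusted p = 0.00628, and adjusted p = 0.653 with an estimated correlation). The list of mitochondrial regulators and the brown fat program had a median of -0.19, and its 2 members that fell were Cox7a1 and Cox8b, which are structural subunits. In that list 21 did not pass, and 3 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.00702, and adjusted p = 0.624 with an estimated correlation). The call of Slc16a1 was lost without WT2, WT3, KO1 or KO2 (adjusted p from 0.0717 to 0.209), as were those of Cox7a1 and Cox8b (0.0811 to 0.279), and all 3 were lost with the hepatocyte covariate (0.0611 to 0.0787). Without KO1 these 2 lists no longer passed, with adjusted p of 0.353 and 0.269. Ppargc1a, a coactivator of mitochondrial gene expression, had 218 ± 51.5 CPM in WT and 155 ± 21.6 CPM in cPrdm16 KO (adjusted p = 0.311). The 7 tested mitochondrially encoded genes had a median of -0.24 and did not pass (camera adjusted p = 0.430, and 0.00298 without WT2), 0 passed when adjusted over the list alone, and mt-Co1 had 11573 ± 1509 CPM in WT and 7918 ± 389 CPM in cPrdm16 KO without passing.

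Matrix genes lay higher in cPrdm16 KO, with 33 of 33 members of the collagen and extracellular matrix list above 0 and a median log2 change of 0.44. Col8a1 rose from 4.28 ± 0.585 to 12.1 ± 0.756 CPM, Fn1 from 507 ± 22.7 to 824 ± 71.8 CPM, and the X-linked proteoglycan gene Bgn from 44.7 ± 11.2 to 102 ± 12.2 CPM. The other 30 did not pass, and 12 rose when adjusted over the list alone (camera adjusted p = 7.8e-08, and adjusted p = 0.540 with an estimated correlation). Fn1 shares exon sequence with Apol7d, and its call was lost whichever library was left out, with adjusted p up to 0.243. The call of Col8a1 was lost without WT3, KO1 or KO2 (0.0675 to 0.158) and that of Bgn without WT2, WT3, KO1 or KO2 (0.0617 to 0.224). The fibroblast list had a median of 0.24 with 14 of 16 members higher and 0 changed, and 4 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.00283, and adjusted p = 0.624 with an estimated correlation). Its member with the smallest p, Meox1, had 18.9 ± 0.379 CPM in WT and 31.5 ± 1.18 CPM in cPrdm16 KO (adjusted p = 0.0553).

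BMP signaling genes lay higher, with 17 of 20 members higher and a median of 0.33. Bmp2, a secreted ligand, rose from 3.65 ± 0.666 to 11.5 ± 0.808 CPM (adjusted p = 0.0198), 19 did not pass, and 6 rose when adjusted over the list alone. Camera gave 0.000263, and adjusted p = 0.399 with an estimated correlation. TGF-beta signaling genes had a median of 0.27 with 22 of 30 higher, 0 changed over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.00283, and adjusted p = 0.399 with an estimated correlation). Tgfb2 was measured at 31.9 ± 2.44 and 46.2 ± 8.42 CPM (adjusted p = 0.167) and Tgfb3 at 19.1 ± 1.69 and 28.9 ± 1.15 CPM (adjusted p = 0.122) in WT and cPrdm16 KO. Without KO2, a fit with 1 cPrdm16 KO library, the TGF-beta list no longer passed (median 0.15) and neither did the fibroblast list (median 0.26). Within Neuregulin and FGF signaling, which did not pass as a list (camera adjusted p = 0.803), Nrg1, a ligand of ErbB receptors, rose from 10.1 ± 1.66 to 39.7 ± 21.1 CPM and Fgf16 fell, and the same 2 genes passed when adjusted over the list alone. Without KO1 the log2 change of Nrg1 went from 1.97 to 1.27 and its call was lost (adjusted p = 0.180), as it was without WT2 (0.0660) or WT3 (0.0725). The call of Bmp2 was lost without KO1 (0.186) or KO2 (0.127), and that of Fgf16 without any 1 library (0.0648 to 0.241).

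Among lists of immune cells, T cell genes and the macrophage list lay higher. The neutrophil and lymphocyte list had a median of 1.25, with 6 of 11 members higher and 5 lower. Its 4 members that rose are all expressed in T lymphocytes or their precursors. Rag1 rose from 2.93 ± 0.738 to 33.2 ± 18.0 CPM, and shares exon sequence with B230118H07Rik. The coreceptor genes Cd8a (log2 change 3.71, SE 0.51) and Cd4 (2.88, SE 0.53) and the kinase gene Lck (2.54, SE 0.43) rose too, and 6 members rose when adjusted over the list alone. Camera gave 0.000221 for the list, and adjusted p = 0.399 with an estimated correlation, and a filter of 1 CPM in 3 libraries, which removes Cd8a, Cd4, Lck, Cd3d and Mpo of the 11 members but keeps Rag1 past the threshold (adjusted p = 0.00887), turned its median to -0.32. Without KO1 the log2 change of Rag1 was 2.79, still past the threshold, while Cd8a (2.97, adjusted p = 0.191) and Lck (1.91, 0.325) were not. The call of Cd8a was also lost without KO2 (0.0521), that of Lck without WT2, WT3 or KO2 (0.0785 to 0.101), that of Cd4 without WT2, WT3, KO1 or KO2 (0.0785 to 0.337), and that of Lyz2 without WT2, KO1 or KO2 (0.0708 to 0.191). The macrophage list had a median of 0.42 with 16 of 16 members higher, of which Lyz2 rose from 23.9 ± 8.72 to 76.8 ± 0.921 CPM and 15 did not pass, while 2 rose when adjusted over the list alone (camera adjusted p = 0.000263, and adjusted p = 0.653 with an estimated correlation).

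The endocardium list had a median of 0.66 with 9 of 9 members higher, 0 changed, and 6 rose when adjusted over the list alone (camera adjusted p = 0.000426, and adjusted p = 0.399 with an estimated correlation). Its member Vwf, the von Willebrand factor gene, had 65.8 ± 6.74 CPM in WT and 104 ± 25.9 CPM in cPrdm16 KO (adjusted p = 0.128). Neural crest and Schwann cell genes had a median of 0.29 with 6 of 8 higher. Mbp, which encodes myelin basic protein, rose from 4.30 ± 1.18 to 18.6 ± 4.72 CPM, 7 did not pass, and 1 rose when adjusted over the list alone (camera adjusted p = 0.0472, and adjusted p = 0.526 with an estimated correlation). The call of Mbp was lost without KO1 (adjusted p = 0.0590) or KO2 (0.127). That list no longer passed without WT1 (adjusted p = 0.256) or KO2 (adjusted p = 0.148).

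Immediate early genes, which respond within minutes to handling and stress, had a median of -0.68 with 25 of 25 members lower, 0 changed, and 0 when adjusted over the list alone (camera adjusted p = 0.000143, and adjusted p = 0.653 with an estimated correlation). Atf3 ranged from 17.0 to 111 CPM in WT and from 7.40 to 25.2 CPM in cPrdm16 KO (adjusted p = 0.248). The list lay at -0.61 in WT1, below KO1 and KO2 (-0.58 and -0.53), and at 0.29 and 0.51 in WT2 and WT3. Interferon response genes had a median of -0.36 with 22 of 22 lower, 0 changed, and 0 when adjusted over the list alone (camera adjusted p = 0.00283, and adjusted p = 0.653 with an estimated correlation), with Gbp3 at an adjusted p of 0.306, and the list no longer passed without WT2 (adjusted p = 0.0789). With WT2 and WT3 left out, an alternative added after the data were seen, the medians of these lists were 0.15 and 0.0014. The cell junction list had a median of -0.22 with 19 of 25 lower, although its changed member Xirp2, an actin-binding protein of intercalated discs, rose from 34.7 ± 0.543 to 66.9 ± 5.34 CPM. There 24 did not pass, and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0209, and adjusted p = 0.698 with an estimated correlation), and the list no longer passed without WT3 (adjusted p = 0.104) or KO1 (adjusted p = 0.302), or with the hepatocyte covariate (0.0566). The call of Xirp2 was lost without WT3, KO1 or KO2 (0.0617 to 0.158).

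**Figure D3:**
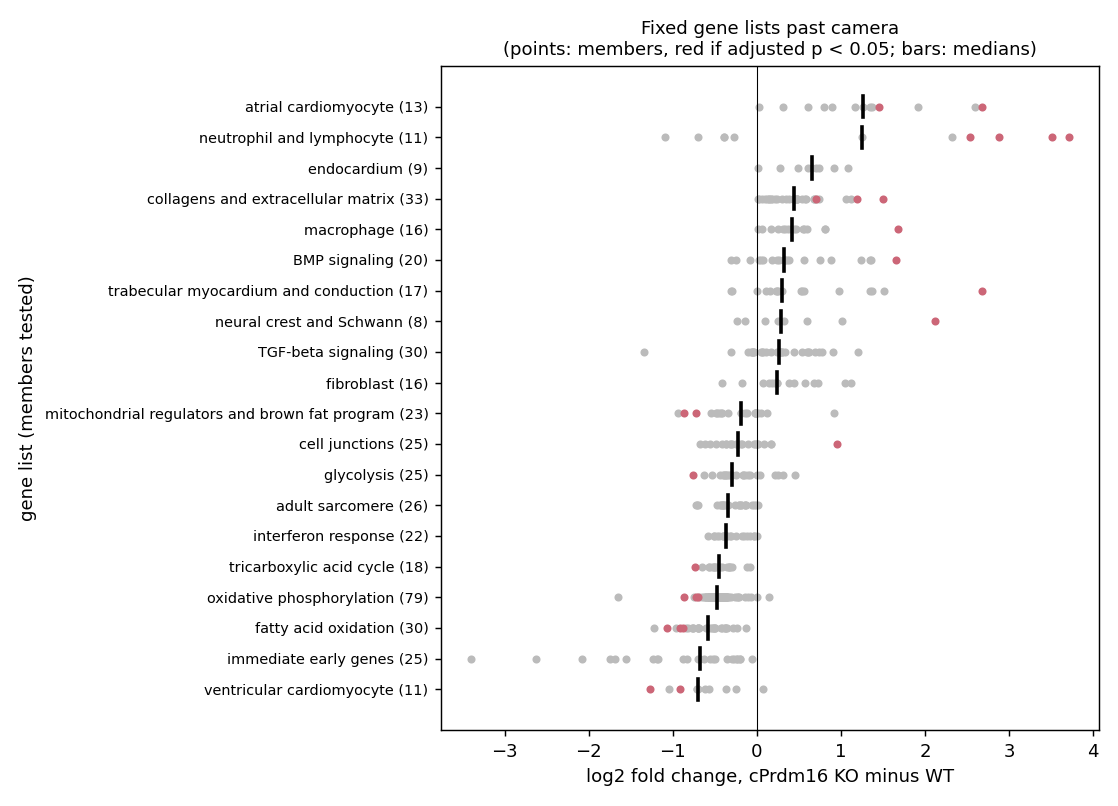
Log2 fold change of cPrdm16 KO minus WT for the members of the 20 lists past camera, with members past an adjusted p of 0.05 in red, other members in grey and list medians as black bars. The medians run from -0.70 for ventricular cardiomyocyte genes to 1.26 for atrial cardiomyocyte genes.

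Altogether 20 of the 43 lists passed camera, 10 upward and 10 downward, and among the 15 cell type lists 6 passed upward and 1 downward. Some lists share members, such as Nppa in the atrial and trabecular lists and collagens in the matrix and fibroblast lists, so these are not separate results. Camera with a correlation estimated per list called 0 lists (smallest adjusted p = 0.399), with 2 at an unadjusted p under 0.05, and fry called 0, with 11 at an unadjusted p under 0.05.

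Several lists that did not pass held changed members. Fetal and stress genes (camera adjusted p = 0.997) contained the rises of Nppa and Xirp2, and 4 rose and 3 fell when adjusted over the list alone. Nppb, the gene of B-type natriuretic peptide, was at 525 ± 273 and 427 ± 221 CPM (adjusted p = 0.854). Myh7, the slow myosin heavy chain gene, was at 11233 ± 3050 and 5444 ± 2288 CPM (adjusted p = 0.169), and Myh6, the fast isoform, at 5937 ± 680 and 4479 ± 2084 CPM (adjusted p = 0.570). Compact myocardium genes had a median of -0.04 and Notch signaling genes, like them, contained the fall of Hey2 (camera adjusted p = 0.896 and 0.654). Both had 1 fall when adjusted over the list alone, and compact myocardium also had 1 rise. Cardiac transcription factors contained the rise of Tbx5 and the fall of Hey2, with 2 rises and 1 fall when adjusted over the list alone (camera adjusted p = 0.0765, 0.0461 without WT2 and 0.0202 without KO2). In the calcium handling list (median -0.15, camera adjusted p = 0.503), Casq1, the calsequestrin of skeletal muscle, rose from 51.9 ± 1.94 to 101 ± 10.4 CPM, and 1 rose and 2 fell when adjusted over the list alone. Kcne1 was the changed member of the ion channel list, where 6 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.782). In the lymphatic endothelium list (camera adjusted p = 0.944), Pdpn, the podoplanin gene, rose from 7.20 ± 0.692 to 17.4 ± 2.32 CPM, and 1 rose and 1 fell when adjusted over the list alone. The calls of Casq1 (0.0617 to 0.127) and Xirp2 (0.0617 to 0.158) were lost without WT3, KO1 or KO2, and that of Pdpn without WT2, WT3, KO1 or KO2 (0.0515 to 0.186).

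The other lists had 0 changed members over all genes tested. Endothelium genes had a median of 0.05 (camera adjusted p = 0.654), with 1 fall when adjusted over the list alone and Cldn5 at an adjusted p of 0.0749. Smooth muscle and pericyte genes had a median of -0.23 (camera adjusted p = 0.297), with 1 rise when adjusted over the list alone and Cnn1 at 30.3 ± 10.5 and 89.0 ± 40.6 CPM (adjusted p = 0.0739). Erythroid genes had a median of 0.23 (camera adjusted p = 0.592), and Tfrc an adjusted p of 0.562. Ribosomal protein genes had a median of -0.05 (camera adjusted p = 0.0612), and Rpl11 an adjusted p of 0.218. Skeletal muscle genes had a median of 0.75 with 6 of 8 members higher (camera adjusted p = 0.141), with 1 rise and 1 fall when adjusted over the list alone and Ckm at 0.136. Their list lay at 0.44 and 0.91 in KO1 and KO2 and at up to 0.29 in WT, and it passed without WT2 (adjusted p = 0.0191), WT3 (0.0136) or KO1 (0.0434). Other lists here that passed with 1 library left out were the S phase list, lower without WT2 (adjusted p = 0.00793), WT3 (0.0416) or KO1 (0.00563), and ribosomal protein genes, lower without WT3 (0.0165) or KO1 (1.51e-07). The epicardium list passed upward without WT2 (0.0360) and the erythroid list without KO1 (0.0486). Camera gave 0.248 for the epicardium (Krt19, adjusted p = 0.212), 0.412 for platelets (Itga2b, 0.594), 0.228 for the S phase (Pcna, 0.212) and 0.228 for G2 and M (Cdc20, 0.389). It gave 0.357 for the integrated stress response (Slc7a11, 0.128), 0.654 for the PRDM family (Prdm6, 0.330), 0.744 for p53 targets (Trp53inp1, 0.302) and 0.817 for hypoxia targets (Higd1a, 0.306). In these 8 lists, and in the erythroid and ribosomal protein lists, 0 members passed when adjusted over the list alone. Fabp4, the tested member of the adipocyte list, had an adjusted p of 0.178. Median, mean and test differed in sign for the endothelium, Notch, ion channel, Neuregulin and FGF, hypoxia, lymphatic endothelium, and fetal and stress lists.

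Liver transcripts differed between libraries within both groups. Alb, the albumin gene, had 2 counts in WT1, 7499 in WT2 and 18401 in WT3, and 1 in KO1 and 3353 in KO2. The thymus and liver list had a median of -1.96 without passing (camera adjusted p = 0.243, and 3.12e-05 without WT1), with Apoa2 at an adjusted p of 0.515 and 0 members changed when adjusted over the list alone. With the level of hepatocyte transcripts as a covariate, 141 genes changed, and 126 of the 181 genes were among them. Fn1 (adjusted p = 0.0743), Tbx5 (0.0611), Cd4 (0.0566), Fgf16 (0.0568) and Banf2os (0.0562) lost their calls with it. The log2 changes of these genes were 0.71, 1.45, 2.76, -1.51 and -2.46 with the covariate. They were 0.70, 1.46, 2.88, -1.47 and -2.46 without it.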

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

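The covariate alternatives and those that left out X and Y genes or WT2 and WT3 were chosen after the data were seen; the others were planned. All 181 genes kept their direction wherever an alternative tested them. Counts near the 181 came from median-ratio factors (180), library sizes without mitochondrially encoded genes (181), limma-voom (165), the stricter filter (135), X and Y genes left out (157) and the hepatocyte covariate (141). Other counts were 383 without a filter, 319 with robust empirical Bayes, 657 with DESeq2, 100 against a fold of 1.2, 26 at an adjusted p under 0.01, 1 with the atrial covariate, and 415 without WT2 and WT3, a fit with 1 residual degree of freedom in which WT1 is assumed to vary like the KO libraries. DESeq2 called 51.4% of its genes higher, against 74.0% in edgeR, and 179 genes were shared. Leaving out 1 library gave 14 (without KO2), 28 (without KO1), 74 (without WT3), 133 (without WT2) and 218 (without WT1), where a lone KO library is assumed to vary like WT. Of 46 changed named genes, 41, 25 and 21 still passed without WT1, WT2 and WT3, 9 without KO1 and 8 without KO2; 7 passed in all 5 of these fits and 5 in none. The replicate block gave 153 genes, 110 of them shared. Whether the numbers pair the hearts cannot be told. Deviations correlated over genes at 0.384 for WT1 with KO1, 0.0681 for WT2 with KO2 and 0.415 for WT3 with KO2. Only 2 pairs exist, and the deviations of KO1 and KO2 from their mean are mirror images. Lists past the test numbered 18 to 24, and cell type lists 5 to 9, with 1 library left out, 10 and 3 with the atrial covariate, and 0 and 0 with fry or an estimated correlation. The cause was not tested for these moves unless the fit had fewer genes or samples. Prdm16 turned from -0.43 to 0.0095 with the atrial covariate and kept its sign otherwise (adjusted p from 0.295 to 0.999 over 17 alternatives).

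Of 23 lists that did not pass, 18 changed the sign of their median under at least 1 alternative. With 1 library left out, reversals gave ranges of -0.37 to 0.046 for smooth muscle and pericyte, -0.57 to 0.012 for mitochondrially encoded genes, -0.27 to 0.50 for erythroid, -0.11 to 0.10 for compact myocardium, -0.18 to 0.14 for endothelium, -0.30 to 0.12 for ribosomal protein genes and -0.97 to 0.15 for Nppb. The stricter filter turned the neutrophil and lymphocyte list to -0.32 by removing Cd8a, Cd4, Lck, Cd3d and Mpo, and the block turned mitochondrially encoded genes to 0.15. The hepatocyte covariate gave 0.37 for thymus and liver and 0.074 for Nppb. The atrial covariate gave 0.69 for mitochondrially encoded genes, -0.10 for erythroid genes and -0.042 for Prdm6. Without WT2 and WT3 the values were 0.029 for compact myocardium, 0.011 for calcium handling, 0.0014 for interferon response, 0.15 for immediate early genes, 0.011 for ribosomal protein genes, -0.057 for endothelium, -0.31 for erythroid, 6.44 for thymus and liver, 1.72 for Apoa2 and 0.97 for Nppb. The cause was not tested.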

Other observations

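The genes, lists and tests in this part were chosen after the data were seen, and so were the bounds of the tests on sex at autosomal genes, on the atrial share at oxidative phosphorylation genes and on the cardiomyocyte share; the bounds of the other tests were written before their results, but weighing the leukocyte lists against their spread within groups was added afterwards. The genes named first are the 4 most abundant rises and the 4 most abundant falls among changed genes with established symbols outside the fixed lists and the genes named above. The imprinted gene Mest rose from 808 ± 48.1 CPM in WT (SD, n = 3) to 1428 ± 46.4 CPM in cPrdm16 KO (SD, n = 2), and Hmcn1, which encodes a large extracellular matrix protein, from 625 ± 29.7 to 1084 ± 87.1 CPM. Gpx3, the secreted glutathione peroxidase, rose from 35.8 ± 12.8 to 319 ± 128 CPM, and Fras1, a basement membrane protein gene, from 95.2 ± 22.7 to 308 ± 48.4 CPM. Fbxo40, an F-box protein gene of muscle, fell from 163 ± 15.0 to 83.4 ± 16.8 CPM, and Lclat1, an acyltransferase acting on lysocardiolipin, from 155 ± 25.8 to 79.2 ± 12.8 CPM. Il13ra1, an interleukin receptor subunit gene, fell from 125 ± 18.2 to 70.0 ± 1.72 CPM, and Sntb1, a syntrophin gene, from 123 ± 17.4 to 62.3 ± 5.15 CPM. Values of Mest, Hmcn1 and Fras1 are uncertain where their exons overlap those of Copg2, Gm20631 and Gm42604.

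More T cell genes rose than the fixed lists held. The receptor genes Trbc1 and Trbc2 rose from 0.292 to 3.19 CPM and from 0.583 to 5.27 CPM, the receptor chain Cd247 to 2.16 CPM (log2 change 3.40, SE 0.46), and the thymocyte gene Themis from 0.630 ± 0.193 to 7.58 ± 3.29 CPM (log2 change 3.59, SE 0.39, adjusted p = 0.00792). Ccr9, a chemokine receptor of thymocytes, rose from 0.383 ± 0.158 to 4.13 ± 3.12 CPM. Trbc1 and Trbc2 are near copies that can share reads, and exons of Cd247, Themis and Ccr9 overlap those of other genes, so these values are uncertain.

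The first pattern is the split of Xist and Y-linked transcripts. All 5 tested X genes known to escape inactivation (Kdm6a, Eif2s3x, Ddx3x, Kdm5c and Pbdc1) lay lower in both cPrdm16 KO libraries than in all 3 WT libraries, with a median of -0.68, as female WT and male cPrdm16 KO embryos would give. Whether sex contributes to the 168 autosomal genes that changed cannot be told apart from the genotype, because no library has a sex that goes against its group. On the X chromosome, 1.36% of the tested genes outside the sex-linked list changed, against 1.07% of the autosomal genes.

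The second pattern is the rise of T lymphocyte genes. Thymocytes carried over with the heart may account for it, but the test made cannot tell them from T cells inside the heart. Either would raise a list of thymocyte genes, and this list was written after other T cell genes were seen to rise. The 7 tested members of the thymocyte list, which leaves out genes seen beforehand, had a median log2 change of 1.94. Of these, 7 of 7 lay above all WT libraries and 1, Cd8b1, was past the threshold. The most abundant tested members of the thymocyte list in cPrdm16 KO were Bcl11b (7.12 CPM in WT, 11.6 CPM in cPrdm16 KO) and Tcf7 (log2 change 1.88, 4.36 CPM in cPrdm16 KO). A general rise in leukocytes cannot be told apart from carried-over thymocytes. The B cell precursor list (3 tested, median -0.061, SD between libraries of a group 0.589) and the granulocyte and NK list (6 tested, median -0.39, SD 1.75) vary too much within groups to decide. The macrophage list lay higher in 16 of 16 members (median 0.42, SD 0.335). It was at -0.49, 0.30 and 0.11 in WT1, WT2 and WT3, against 0.48 and 0.46 in KO1 and KO2. The fixed thymus and liver list, which names the thymus genes Foxn1, Psmb11 and Prss16, cannot decide on carried-over thymus, because most of its members are liver genes. Of its 13 members 10 were tested, and 0 were higher in cPrdm16 KO. Its level ran from -4.75 in WT1 to 3.07 in WT3, much as the hepatocyte list did (-5.60 to 3.53). It thus reads liver content and does not show that thymus genes failed to rise. T cells inside the mutant hearts, or a difference tied to sex or genotype, stay open and untested.

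The third pattern is the higher atrial and lower ventricular and mitochondrial transcripts. Whether a bias against short transcripts is the whole source of the lower oxidative phosphorylation genes was not decided. Their median of -0.48 lay at percentile 0 of 10000 random lists matched on expression and exon length. Those lists also lay lower, at a median of -0.17 and a lowest of -0.36. Genes drawn at random do not move together, and this list also reached percentiles 0 and 100 of expression-matched lists between WT libraries. A lower share of cardiomyocytes alone would raise the other cell types alike. Instead, endocardium exceeded endothelium genes by 0.541 or more in the cPrdm16 KO libraries and by 0.129 or less in WT. List medians were 0.24 for fibroblasts, 0.42 for macrophages, 0.05 for endothelium and -0.23 for smooth muscle and pericytes. A lower share is thus not excluded as a part of the pattern. A larger atrial share of the dissected tissue may contribute to the rises, which was not decided. The percentiles that follow again come from genes drawn at random, which do not move together, so they cannot decide it. The 124 autosomal genes that rose outside the atrial list were higher in WT2 than in WT3 by a median of 0.27 (percentile 100). This compares with 1.79 between genotypes, for a difference in atrial genes of 1.67 between WT2 and WT3. In WT2 against WT1 the 124 genes were higher by 0.09 (percentile 97.5) for an atrial difference of 0.92. In WT1 against WT3 they were higher by 0.21 (percentile 100) for an atrial difference of 0.77, so they did not follow its size. The 42 genes that fell differed by -0.09 in WT2 against WT3 (percentile 6.27) and by -0.19 in WT1 against WT3 (percentile 0). In WT2 against WT1 they differed by 0.07 (percentile 83.7). The ventricular list differed by -0.08, -0.06 and 0.05 in these pairs, in that order (percentiles 21.3, 57.0 and 42.6). Between genotypes its median was -0.70, for a median of 1.26 in the atrial list. For the ventricular list, these values from 3 WT libraries argue against a larger atrial share as the only source of its fall. Whether a larger atrial share lowers oxidative phosphorylation genes was not decided, because the WT pairs went in both directions. The more atrial library had the higher median in WT2 against WT3 (0.09, percentile 99.96) and WT2 against WT1 (0.29, percentile 100). It had the lower median in WT1 against WT3 (-0.17, percentile 0). With the atrial level as a covariate the median size of the 181 changes went from 1.504 (median SE 0.23) to 1.27 (median SE 0.35) and 1 call was left, with the SE growing by a larger share than the changes shrank. The Y-linked Ddx3y, Uty and Eif2s3y lost their calls too, so the lost calls do not by themselves show that atrial content accounts for the changes. A shift of gene expression toward an atrial state in the mutant hearts stays open.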
